A study of Mus musculus with 4 samples.

How the data were processed

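Total RNA of embryonic mouse kidneys was hybridised to 4 one-colour Agilent arrays, 2 of control and 2 of Sall1 knockout kidneys, with Cy3-labelled cRNA made from 0.25 µg of RNA, per the labels. Groups were taken from the genotype in the labels and replicates were numbered in the order of the samples. The deposited scanner files were made with Agilent Feature Extraction 10.7.3.1 for array design 028005, built on mouse genome mm9, per the file headers. Their processed signal is an intensity on a linear scale that the software had corrected for background and for trends within the array, with no scaling between arrays, per the file headers. The deposited value table holds the same intensity: of 55249 rows with a single spot, 100% equalled the scanner signal within 1%, and its column medians were 52.29 and 47.07 for the control and 47.76 and 45.79 for the knockout arrays. It was used as an alternative source of values. The file of control replicate 1 is written to 3 significant digits. All 4 arrays lay on 1 slide and belonged to 1 scan, so slide and date give no batches.

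Each array held 62976 spots, 59305 of them not controls, for 55681 probes. No spot was saturated, and between 147 and 174 spots per array carried outlier marks. The 75th percentile of the processed signal was 597 and 547.5 in the control and 534 and 521 in the knockout arrays. Signals were set to log2 after division by this percentile. Control spots and spots marked as outliers were left out, the spots of a probe were averaged, and 34253 probes well above background on both arrays of at least 1 group were kept. Gene symbols came from the RefSeq accession in the scanner files, matched without versions to a table of assembly GRCm38.p6: 26413 probes matched and 29268 did not, of which 16194 are given as mm9 intervals. Each gene was represented by the probe with the highest mean, for 3869 genes chosen among several probes. Probes not used that differed in the other direction from the named gene were those of Fut9 (-0.50), Etv1 (-0.37), Fgf8 (0.20) and Star (0.48), each below background on most arrays, and of Pax2 (-0.033), Sall4 (-0.30) and Tnfrsf19 (0.12). In all, 15083 named genes and 9993 unnamed sequences were tested.

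Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, default prior), with Benjamini-Hochberg adjustment over all genes tested, with 2 residual and 1.79 prior degrees of freedom. Standard errors are those of this fit. For a probe not well above background on every array of a group, the fold is a lower bound: the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own signal and the lowest signal well above background on the array. Gene lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, adjusted over 24 lists with at least 5 tested members; Sall1 is in no list. A description without a test counted genes at least 1.5-fold apart with both knockout values beyond both control values, beside the same count in the other splits of the arrays.

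The groups, tests, 25 lists and most alternatives were fixed before the data were examined. Genes were named by rule: Sall1; in each direction 12 named genes with the largest fold among those past the threshold without overlap, filled with the smallest unadjusted p where fewer passed; up to 4 members of each list by unadjusted p; and a fixed set of regulators of the kidney (Six2, Cited1, Osr1, Eya1, Gdnf, Itga8, Pax2, Wt1, Wnt4, Lhx1, Ret, Wnt11, Foxd1, Sall4 and Cdkn1a). RIKEN, Gm and LOC names were passed over in the second part. Other members of a list named in the text passed when adjusted over the list alone. Some genes that these rules name are not reported here. Lists of intercalated cell, principal cell and retinoid pathway genes were written after the first results were seen, with members whose values had not been looked at.

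The alternatives were normexp background correction (offset 50), quantile normalization, median centring, no background filter, probes above background on all 4 arrays, marked spots kept, the mean over the probes of a gene, a trended and robust variance prior (trended alone in camera), array weights, the deposited value table, each array left out in turn, a 2-fold limit, an adjusted p under 0.1, and camera with an estimated correlation or fry. The mean spot signal is not among the columns used here, so normexp ran on the median signal. Limma and camera were tested on simulated data for this comparison: over 10 runs of 200 changed genes among 25076, 0.4% of 1.5-fold, 39.6% of 2-fold, 81.4% of 4-fold and 92.2% of 8-fold changes were recovered with the default prior, and 36.4%, 68% and 90.2% of the first 3 sizes with the trended robust prior, which called 0.0281% of unchanged genes. Simulated variances were drawn from the trended prior fitted to these arrays, with independent normal errors. This favours the trended robust prior in advance. Its recovery and its few false calls therefore do not test it for the real arrays. Camera called 10 of 10 lists of 20 genes shifted by 0.4 on the log2 scale and 0 of 500 unshifted lists of independent genes. Independent genes suit the preset correlation of 0.01 in advance, so this does not test camera for the real lists. Estimated correlations there ranged from -0.082 (adrenal cortex and gonad) to 0.98 (skeletal muscle), with 0.12 for nephron progenitor, 0.39 for macrophage and 0.76 for liver genes. Intervals of medians are 95% bootstrap intervals over genes from 10000 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.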

Results

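Gene expression was measured in embryonic mouse kidneys at E13.5, 24 hours after tamoxifen was given at E12.5. Tamoxifen activates CreER, a fusion of Cre recombinase with the ligand-binding part of an oestrogen receptor, and here was used to delete Sall1, which encodes a zinc finger transcription factor of the embryonic kidney. Of the 4 arrays, 2 carried RNA of control kidneys and 2 carried RNA of Sall1 knockout kidneys, all from a hybrid strain background. Each array held 62976 spots, and the share of spots well above background was 64.1% and 63.3% in the control arrays and 64.2% and 60.6% in the knockout arrays. Across probes, which are not independent replicates, Pearson's r was 0.9952 between the control arrays, 0.9964 between the knockout arrays and 0.9932 to 0.9945 between arrays of different groups. The labels do not say whether a sample was a single embryo or a pool, so the p-values measure the spread between these samples, and the number of arrays limits the precision.

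The first question was whether the targeted gene itself differed. Sall1 was 1.68-fold lower in the knockout kidneys, with log2 signals of 1.79 and 1.81 in the control arrays and 1.03 and 1.07 in the knockout arrays, relative to the 75th percentile of each array. The log2 difference was -0.75 ± 0.056 (SE, n = 2 per group), and both knockout values lay below both control values. In limma it did not pass over all genes tested (adjusted p = 0.126), while a variance prior that follows the signal gave an adjusted p of 0.00143 and normexp background correction gave 0.0383. Sall1 was measured by 1 probe, and whether this probe lies inside the deleted part is not given in the sources used here, so it does not check the deletion itself.

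The second question was which genes differed after loss of Sall1. Cited1, a transcriptional co-regulator that marks uncommitted nephron progenitors, was 4.60-fold lower in the knockout kidneys (log2 difference -2.20 ± 0.082, SE). Stk32a, a protein kinase gene, was 7.76-fold lower, Ocm, the calcium-binding oncomodulin, 6.07-fold lower and Chl1, a cell adhesion molecule of the L1 family, 4.15-fold lower. In the other direction Tenm2, a teneurin cell-surface protein, was 5.57-fold higher (log2 difference 2.48 ± 0.068, SE). Pdzk1, a scaffold protein of the proximal tubule brush border, was 3.11-fold higher, and Zfp536, a zinc finger protein, was 2.54-fold higher. None of these genes passed over all genes tested in limma, where the adjusted p was 0.0818 for Cited1, Stk32a, Chl1, Pdzk1 and Zfp536, 0.0724 for Tenm2 and 0.102 for Ocm.

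Further genes with the smallest unadjusted p, none of which passed, extended both directions. Lower in the knockout kidneys were St6galnac5 by 3.16-fold, Fam155a by 2.46-fold, Npr3, the clearance receptor for natriuretic peptides, by 2.40-fold, Snap91, a clathrin assembly protein, by 2.16-fold, and the keratin Krt23 by 2.04-fold. Aldh1a1, which makes retinoic acid from retinaldehyde, was 2.03-fold lower. Cyp26a1, which degrades retinoic acid, and Lamp5 were not well above background on either knockout array and were at least 2.87-fold and at least 1.76-fold lower. Higher in the knockout kidneys were Iqcf4 by 3.71-fold, Slitrk6 by 2.63-fold, Cldn1, a tight junction protein, by 2.46-fold, the small GTPase Diras2 by 2.41-fold, Efhd1 by 2.10-fold and Trhr, the receptor for thyrotropin-releasing hormone, by 2.09-fold. Esr1, the oestrogen receptor gene, Ccdc121 and Cngb3 were not well above background on either control array and were at least 2.83-fold, at least 2.53-fold and at least 1.49-fold higher. The other 2 Esr1 probes were not well above background on any array and differed by 0.22 and 0.17 on the log2 scale, and the other Ccdc121 probe, above background on 1 knockout array, differed by 0.57. The other Stk32a probe, below background in the knockout arrays, differed by -1.14. For Iqcf4 the other probe was not well above background on any array and differed by 0.21.

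**Figure D1:**
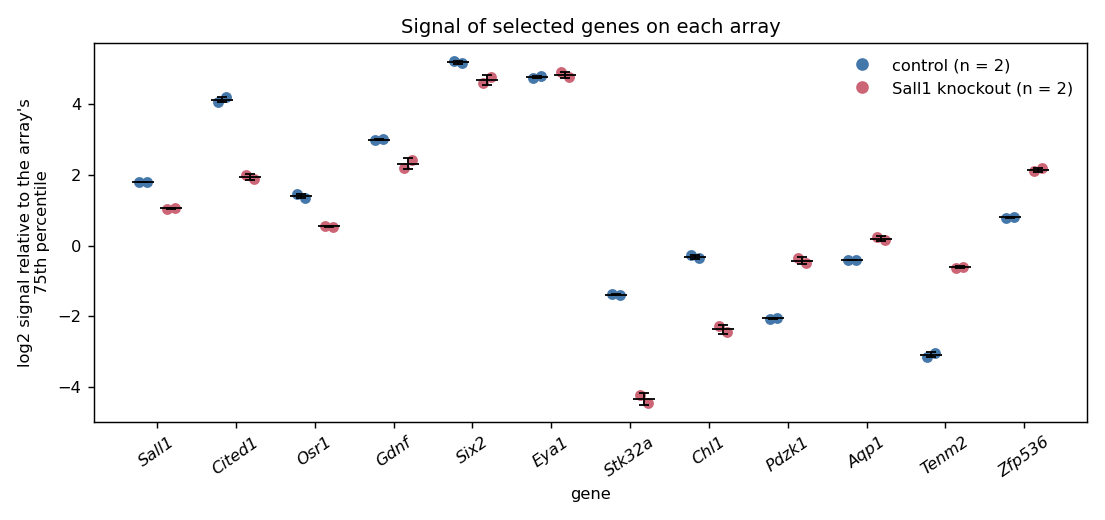
Log2 signal relative to the 75th percentile of each array (vertical axis) for 12 genes (horizontal axis) on the 2 control arrays (blue) and the 2 Sall1 knockout arrays (red); bars show the mean and SD. The mean of Cited1 was 4.14 in control and 1.94 in knockout kidneys, whereas the groups of Eya1 differed by 0.062.

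Over the 25076 genes and unnamed sequences tested, limma called 0 higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.0724. At an unadjusted p under 0.05 there were 1699 higher and 1490 lower, where chance alone gives 1254 in all. At an adjusted p under 0.1 there were 11 higher and 10 lower. The prior that follows the signal called 136 higher and 164 lower, and normexp correction called 19 higher and 22 lower. Of the nephron progenitor genes, 7 were called lower under that prior, namely Cited1, Gdnf, Itga8, Meox2, Osr1, Rspo1 and Six2, and of the proximal tubule genes Aqp1, Cdh16 and Pdzk1 were called higher. Under the same prior the liver genes Apoa2 and Trf, the stromal genes Fibin and Penk, the ureteric bud genes Krt19 and Tfcp2l1, the p53 response genes Ccng1 and Cdkn1a, and Cldn5, Cx3cr1, Sostdc1 and Il17rd were called higher. Robo2, Nefl, Mc2r, Des and Tnfrsf19 were called lower. In data simulated for this comparison on 25076 genes, limma with its default prior recovered 0.4% of genes changed 1.5-fold, 39.6% of those changed 2-fold and 81.4% of those changed 4-fold. Variances there were drawn from the prior that follows the signal, so these shares may not hold for the real arrays. In the real arrays Stk32a, 7.76-fold lower, did not pass. The titles of the control samples name flox, and those of the knockout samples alone name CreER. An effect of CreER therefore cannot be separated from that of Sall1, and litters are not given in the labels.

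Without a test, 887 genes or unnamed sequences differed by at least 1.5-fold with no overlap of the groups, 623 higher and 264 lower in the knockout kidneys. Among those with a gene symbol, 464 were higher and 148 lower. The other splits of the 4 arrays into pairs gave 443, for both second replicates against both first, and 167. At any fold, the groups did not overlap for 49.2% of genes, against 30.0% and 20.8% in the other splits and 33.3% by chance. Without ties each gene separates in a single split, so a larger share in 1 split lowers the others. The other splits are therefore no independent background for these shares and counts. The count was 231 with normexp correction, 586 for probes above background on all 4 arrays, and 1453 without control replicate 1, 1474 without Sall1 knockout replicate 1, 1519 without control replicate 2 and 1649 without Sall1 knockout replicate 2, where 1 array stands for a group and overlap is less frequent.

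The third question was which cell types and pathways of the fetal kidney shifted, tested on gene lists fixed before the data were examined. By limma's camera with a preset correlation of 0.01 between genes, 12 of 24 lists were called at an adjusted p under 0.05, 9 higher and 3 lower. With a correlation estimated for each list 0 lists were called, with a smallest adjusted p of 0.444 and 1 list, proximal tubule, at an unadjusted p under 0.05. The self-contained test fry called 0 lists in one direction, with a smallest adjusted p of 0.0699 and 5 lists at an unadjusted p under 0.05, and called 16 lists when either direction counted. No member of any list passed over all genes tested, so the counts given per list are adjusted over the list alone.

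**Figure D2:**
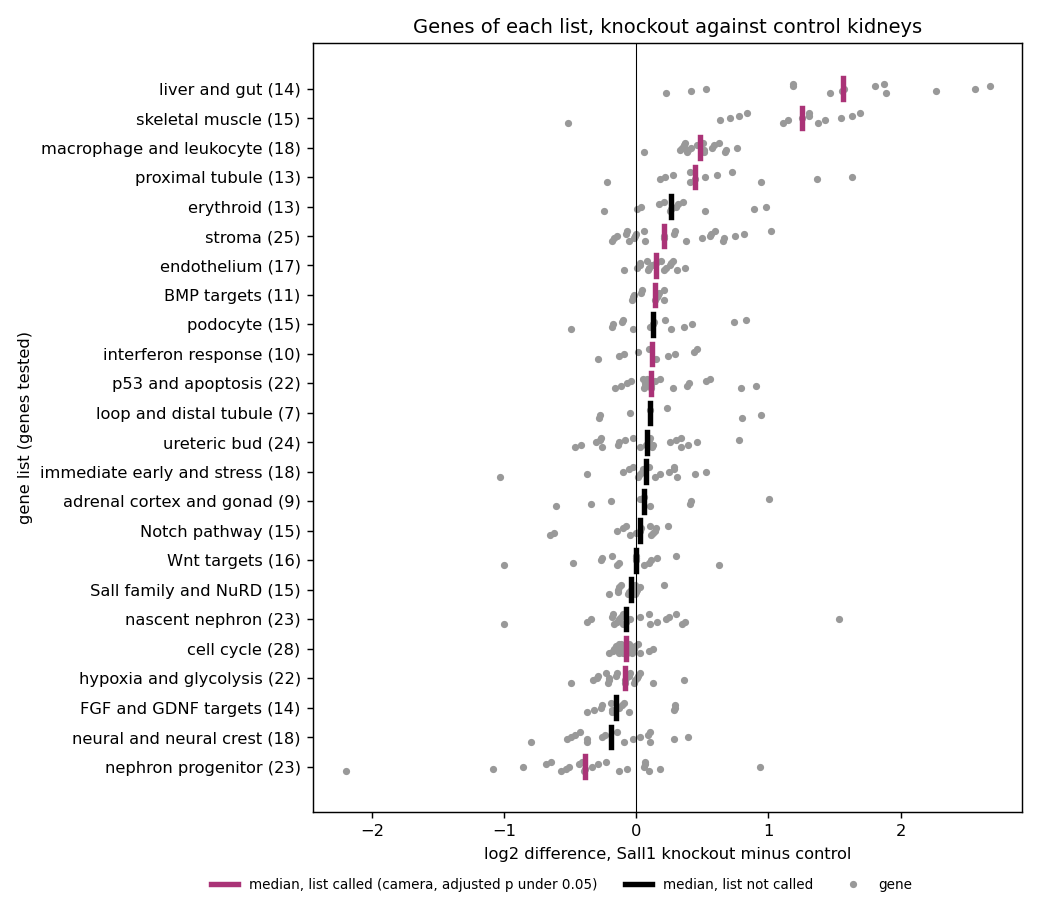
Log2 difference between Sall1 knockout and control kidneys (horizontal axis) for the genes of each of 24 lists (vertical axis, with the number tested); grey points are genes, thick bars are medians, purple where camera with the preset correlation called the list. Nephron progenitor genes had the lowest median at -0.39, and liver and gut genes the highest at 1.57.

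Genes of the nephron progenitors, the self-renewing cap mesenchyme that gives rise to nephrons, fell in the knockout kidneys with a median log2 difference of -0.39 over 23 genes. Of these, 12 were lower, 0 were higher and 11 did not pass when adjusted over the list alone. Besides Cited1 they included Osr1 (1.81-fold lower), Gdnf, the ligand that drives ureteric bud branching (1.61-fold lower), Meox2 (1.48-fold lower) and Six2, the transcription factor that keeps progenitors undifferentiated (1.42-fold lower; log2 difference -0.51 ± 0.090, SE). Spock2 was 2.12-fold, Hoxa11 1.44-fold, Uncx 1.35-fold, Rspo1 1.33-fold, Hoxd11 1.31-fold, Itga8, the integrin that maintains Gdnf expression, 1.26-fold and Bmp7 1.23-fold lower. Other regulators of the same cells did not pass: the log2 difference was 0.062 ± 0.071 (SE) for Eya1, 0.060 ± 0.062 for Wt1 and 0.18 ± 0.084 for Pax2. Camera gave an adjusted p of 6.29e-06 with the preset correlation, and an adjusted p = 0.444 with an estimated correlation. Markers of adjoining tissues were higher in the same arrays, by a median of 1.57 for liver and gut and 1.25 for skeletal muscle.

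Genes of the nascent nephron, the renal vesicles and their descendants, were not called (23 genes, adjusted p = 0.947 in limma's camera). Their median log2 difference was -0.079, turning to 0.034 without control replicate 2, whereas their mean was 0.018 and the test leaned higher. Dkk1, an inhibitor of Wnt signalling, was 2.01-fold lower and Fgf8, which nascent nephrons need to survive, was 1.27-fold lower, while Irx1 was 2.89-fold and Npy 1.23-fold higher. Of the 23 genes, 0 passed in limma when adjusted over the list alone, with 6 higher and 4 lower at an unadjusted p under 0.05. The log2 difference was -0.049 ± 0.062 (SE) for Wnt4, the signal that starts epithelial conversion, and -0.19 ± 0.054 for Lhx1.

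Genes of the proximal tubule, the segment that reabsorbs most of the filtrate, rose in the knockout kidneys with a median log2 difference of 0.45 over 13 genes. Of these, 9 were higher, 0 were lower and 4 did not pass when adjusted over the list alone. Besides Pdzk1 they included the water channel Aqp1 (1.53-fold higher), the organic anion transporter Slc22a6 (1.43-fold higher), Fut9 (1.66-fold higher), and the endocytic receptor Lrp2, whose log2 difference was 0.41 ± 0.077 (SE). Camera gave an adjusted p of 6.37e-08, and an adjusted p = 0.444 with an estimated correlation. Liver and gut genes were higher in the same arrays by a median of 1.57, and Hnf4a, Pdzk1 and Spp2, among the tubule genes, are also made by liver. Of the 12 lists called with the preset correlation 9 were higher, so a rise was not particular to this list. Whether other cells of the kidney made these transcripts was not tested.

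The other nephron segments were not called as lists. Podocyte genes had a median log2 difference of 0.12 over 15 genes (adjusted p = 0.153), with the receptor phosphatase Ptpro 1.67-fold higher and Robo2 1.41-fold lower, both passing when adjusted over the list alone. Nes was 1.16-fold higher without passing. Genes of the loop of Henle and distal tubule had a median of 0.10 over 7 genes (adjusted p = 0.410), turning to -0.073 without control replicate 1, and Sostdc1, an antagonist of BMP and Wnt signals, was 1.92-fold higher and passed over the list alone.

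Genes of the ureteric bud, the epithelium that forms the collecting ducts, moved in both directions and were not called (24 genes, median 0.081, adjusted p = 0.446). Their median was 0.034 without control replicate 1 and 0.034 without Sall1 knockout replicate 2. When adjusted over the list alone, 3 were higher, namely the keratin Krt19 (1.71-fold), the collecting duct transcription factor Tfcp2l1 (1.37-fold) and Gata2 (1.26-fold). Lower over the list alone were 4 genes, among them Sox8, Slco4c1 and Ret, the Gdnf receptor of the bud tip, with a log2 difference of -0.28 ± 0.058 (SE). Wnt11, a bud tip gene that depends on Ret signalling, differed by -0.26 ± 0.084 and did not pass. Targets of FGF and GDNF signalling had a median of -0.16 over 14 genes and were not called (adjusted p = 0.0733). Of these Il17rd and Etv1 were higher and Egr1 lower over the list alone.

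Stromal genes rose by a median of 0.21 over 25 genes (adjusted p = 0.00964 in camera, adjusted p = 0.641 with an estimated correlation). Fibin was 1.68-fold and Penk, which encodes proenkephalin, 1.58-fold higher and both passed over the list alone, whereas Foxd1, the transcription factor of cortical stroma progenitors, differed by -0.17 ± 0.10 (SE). Log2 signals of Foxd1 were 2.91 and 2.68 in the control and 2.59 and 2.67 in the knockout arrays, so its difference rests largely on control replicate 1. Lum and Col3a1, of the extracellular matrix, were 1.76-fold and 1.30-fold higher without passing. Skeletal muscle genes were higher in the same arrays by a median of 1.25. The median was 0.42 without control replicate 1 and 0.34 without Sall1 knockout replicate 2, and the call was lost without control replicate 2 (0.056, adjusted p = 0.108) and without Sall1 knockout replicate 1 (0.13, adjusted p = 0.0809). With no background filter the adjusted p was 0.0712.

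Endothelial genes rose by a smaller amount, a median of 0.14 over 17 genes, with 0 of them passing over the list alone and 8 higher at an unadjusted p under 0.05 (adjusted p = 2.04e-05 in camera, adjusted p = 0.444 with an estimated correlation). The smallest unadjusted p belonged to the tight junction gene Cldn5 (1.29-fold), Tek (1.24-fold), Sox17 (1.21-fold) and Eng (1.19-fold), all higher in both knockout arrays. Macrophage and leukocyte genes rose by a median of 0.48 over 18 genes, of which 11 were higher, 0 were lower and 7 did not pass over the list alone (adjusted p = 3.04e-09 in camera, adjusted p = 0.444 with an estimated correlation). Cx3cr1, a chemokine receptor of tissue macrophages, was higher by 0.59 ± 0.11 (SE) on the log2 scale, the Fc receptor Fcgr3 was 1.49-fold, Aif1 1.43-fold and Ptprc, the pan-leukocyte marker, 1.30-fold higher. Liver and gut genes were higher in the same arrays by a median of 1.57.

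Markers of tissues next to the kidney also moved with the groups. Liver and gut genes rose by a median log2 difference of 1.57 over 14 genes, of which 9 were higher and 5 did not pass over the list alone (adjusted p = 3.04e-09 in camera, adjusted p = 0.535 with an estimated correlation). Ttr was 3.49-fold, Apoa1 2.98-fold, Afp, which encodes alpha-fetoprotein, 2.76-fold and Trf, which encodes transferrin, 2.27-fold higher. Skeletal muscle genes rose by a median of 1.25 over 15 genes, with 0 passing over the list alone and 3 higher and 1 lower at an unadjusted p under 0.05 (adjusted p = 0.000187 in camera, adjusted p = 0.642 with an estimated correlation). Acta1 was 2.47-fold, Myl1 2.39-fold and Myl4 2.22-fold higher, whereas Des was 1.43-fold lower. Both lists also differed between the control arrays, with medians of 0.79 for liver and gut and -1.06 for muscle, control replicate 2 minus control replicate 1. Between the knockout arrays, replicate 2 minus replicate 1, the medians were -0.13 and -0.56. Without control replicate 2 the muscle median was 0.45.

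Erythroid genes were not called (13 genes, median 0.26, adjusted p = 0.308 in camera) and differed between the control arrays by a median of 1.60. Their median was -0.47 without control replicate 1 and -0.24 without Sall1 knockout replicate 2, and 1.01 without control replicate 2 and 0.79 without Sall1 knockout replicate 1, when they were called. Neural genes had a median of -0.19 over 18 genes and were not called (adjusted p = 0.0733), with Nefl, Nefm and Stmn2 1.74-fold, 1.41-fold and 1.38-fold lower over the list alone. Their median was 0.014 without control replicate 2 and -0.043 without Sall1 knockout replicate 2, and they were called without control replicate 1 (-0.56) and without Sall1 knockout replicate 1 (-0.20). Adrenal cortex and gonad genes were not called (9 genes, median 0.055, adjusted p = 0.692, and 0.012 to 0.085 with single arrays left out), and Mc2r, the corticotropin receptor, was 1.53-fold lower over the list alone. Of the sex-linked genes only Xist was tested, with a log2 difference of -0.027 ± 0.059 (SE), and 0 of 5 Y-linked probes were well above background on any array.

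**Figure D3:**
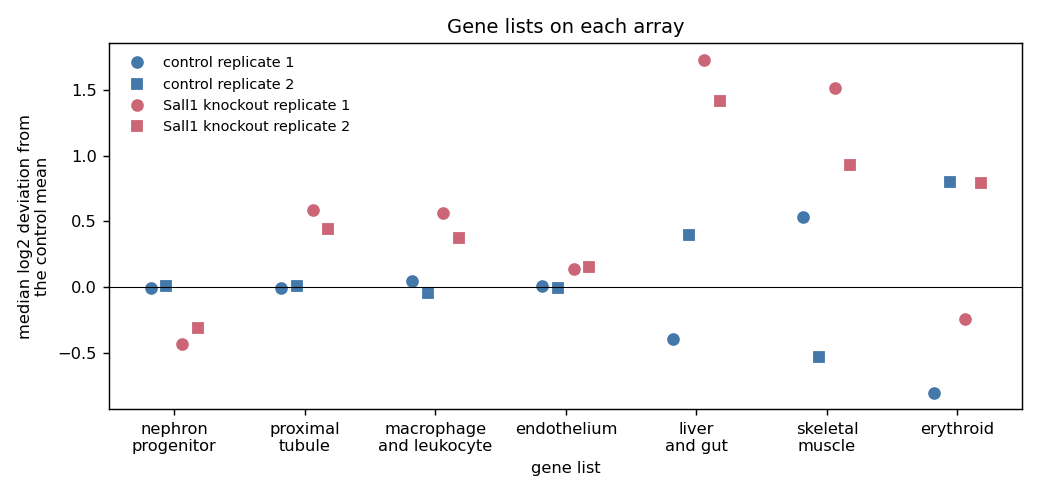
Median log2 deviation from the control mean (vertical axis) of 7 gene lists (horizontal axis) on each array; blue marks control arrays, red Sall1 knockout arrays, circles replicate 1 and squares replicate 2. Nephron progenitor genes lay at -0.43 and -0.31 and proximal tubule genes at 0.59 and 0.44 in the knockout arrays, while liver, muscle and erythroid genes also differed between the control arrays.

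Genes of the p53 response and apoptosis rose by a median of 0.11 over 22 genes (adjusted p = 0.00167 in camera, adjusted p = 0.444 with an estimated correlation). The cell cycle inhibitor Cdkn1a was 1.47-fold and Ccng1 1.30-fold higher and both passed over the list alone, while Pmaip1, which encodes the pro-apoptotic Noxa, was 1.87-fold and Trp53inp1 1.21-fold higher without passing. Cell cycle genes fell by a median of 0.083 over 28 genes, 0 of them passing over the list alone and 2 lower at an unadjusted p under 0.05 (adjusted p = 0.00809 in camera, adjusted p = 0.735 with an estimated correlation). Mcm7, Mcm3 and Mcm2, of the replicative helicase, were 1.16-fold, 1.13-fold and 1.11-fold lower. The p53 median was 0.035 without control replicate 1, 0.073 without Sall1 knockout replicate 2 and 0.17 without control replicate 2. The cell cycle call was lost with quantile normalization (adjusted p = 0.106), without control replicate 2 (median -0.049) and without Sall1 knockout replicate 1 (-0.049). The liver and gut genes (1.57) and skeletal muscle genes (1.25) moved in the same arrays.

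Genes of hypoxia and glycolysis fell by a median of 0.088 over 22 genes (adjusted p = 0.0276 in camera, adjusted p = 0.657 with an estimated correlation), among them the glycolytic genes Hk2, Pgk1 and Ldha with log2 differences of -0.49, -0.33 and -0.30, while Ndrg1 was 1.29-fold higher. Of the hypoxia and glycolysis genes 0 passed over the list alone, with 1 higher and 3 lower at an unadjusted p under 0.05. Interferon response genes rose by a median of 0.12 over 10 genes (adjusted p = 0.0276 in camera, adjusted p = 0.444 with an estimated correlation), with Usp18 and Rsad2 higher over the list alone by 0.46 and 0.43. BMP targets rose by a median of 0.14 over 11 genes (adjusted p = 0.0247 in camera, adjusted p = 0.444 with an estimated correlation), with Id1 higher by 0.21, Id4 by 0.21 and Id3 by 0.16. Of the BMP targets 0 passed over the list alone in limma and 1 at an unadjusted p under 0.05. These 3 calls were lost in several settings: hypoxia without control replicate 1, without Sall1 knockout replicate 1 and over the mean of probes, with -0.13 without Sall1 knockout replicate 2; interferon without any of control replicate 1, control replicate 2 and Sall1 knockout replicate 1, with normexp, over the mean of probes, with a variance prior that follows the signal (adjusted p = 0.0507) and with no background filter, where the median was -0.038. The BMP call was lost without control replicate 2 (0.061), without Sall1 knockout replicate 2 (0.11), with normexp and with no background filter, and the interferon median was 0.26 without Sall1 knockout replicate 2. In the same arrays the median was 1.57 for liver and gut and 1.25 for skeletal muscle genes.

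The remaining pathways were not called by camera. Wnt targets had a median of -0.0051 over 16 genes (adjusted p = 0.518), with Tnfrsf19 (1.39-fold) and Dkk1 lower over the list alone, although the other Tnfrsf19 probe differed by 0.12. Notch pathway genes had a median of 0.027 and a mean of -0.049 over 15 genes (adjusted p = 0.542), and Hey2 was 1.57-fold lower without passing. Immediate early and stress genes had a median of 0.073 over 18 genes (adjusted p = 0.301), 0.16 without control replicate 1 and 0.023 without control replicate 2, with Egr1 1.30-fold lower and Hspb1 1.36-fold higher without passing. Genes of the Sall family and of the NuRD chromatin complex, which Sall proteins bind, had a median of -0.040 over 15 genes (adjusted p = 0.198), -0.064 without control replicate 1, and Sall4 differed by 0.027 ± 0.060 (SE), a value of -0.14 over the mean of its probes.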

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

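No paired analysis was run because the groups share no replicate number in the labels. The series design speaks of 2 sets without saying which samples form one, so pairing by litter or set stays open. Replicate 2 minus replicate 1 had the same sign in both groups for erythroid (1.60 in control, 0.90 in knockout) and muscle genes (-1.06, -0.56), while 1 slide and 1 scan left no batch to block. Of the other called lists, nephron progenitor, stroma, macrophage, p53 and cell cycle genes also had the same sign in both groups. The sign was opposite for proximal tubule, endothelium, liver, hypoxia, interferon and BMP genes. Replicates were numbered in the order of the samples, so the numbers pair no samples. Exchanging them in 1 group would turn each same sign into an opposite one. These signs therefore cannot tell which lists differ between sets. Counts of called genes were 0 higher and 0 lower in limma in all settings other than these: normexp on the median signal gave 19 higher and 22 lower, the trended robust prior 136 higher and 164 lower, and an adjusted p under 0.1 gave 11 higher and 10 lower. The cause was not tested. Of the 24 genes named for the smallest unadjusted p, 22 were called under that prior and 16 with normexp; of all 126 named genes other than Sall1, 44 and 19 passed, and 0 in the other settings at an adjusted p under 0.05. The log2 difference of Sall1 passed with normexp (-0.72) and the trended prior (-0.75) and ranged from -0.77 to -0.73 when single arrays were left out, without passing.

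The count of 887 genes at least 1.5-fold apart became 231 with normexp, whose added offset of 50 narrows the folds of dim probes. How much of the drop this gives was not tested. The count became 2927 with no background filter, 586 for probes above background on all 4 arrays, 279 at 2-fold, and 1453 to 1649 with an array left out, where a single array overlaps less. The 12 called lists became 0 with an estimated correlation and 0 with fry. With an array left out, 1 group holds a single array and gives no spread of its own. Calls kept, lost or gained in those 4 of the 14 alternatives rest on the spread of the other group. Camera called the nephron progenitor, endothelium, macrophage, muscle, liver, p53 and proximal tubule lists in all 14 alternatives, with a progenitor median of -0.43 to -0.31 and a tubule median of 0.39 to 0.59. The stroma list kept its call in 12 of 15 (1 of the 15, without Acta2 and Tagln, was chosen after seeing the data), cell cycle and hypoxia in 11 of 14, BMP targets in 10 of 14 and interferon in 7 of 14. Lists not called in the first place were called in 5 of 14 (neural), 4 of 14 (FGF and GDNF targets), 2 of 14 (erythroid) and 1 of 14 (Sall family and NuRD).

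Signs turned for the interferon list with no background filter (-0.038), the Wnt list over the mean of probes (0.020) and in the value table (0.0011), the Sall family and NuRD list with quantile normalization (0.0085), Star with normexp (0.017) and Sall4 over the mean of probes (-0.14). Without 1 array at a time, medians ranged from -0.073 to 0.15 for loop and distal tubule, -0.47 to 1.01 for erythroid, -0.014 to 0.067 for Notch, -0.073 to 0.019 for Wnt, -0.082 to 0.034 for nascent nephron and -0.56 to 0.014 for neural genes. Over the same settings log2 differences ranged from -0.28 to 0.91 for Tspo2, -0.78 to 1.82 for Hbb-b2, -0.055 to 0.0020 for Xist and -0.0066 to 0.061 for Sall4. The cause was not tested. Signal over background limits the values of Star, Esr1, Ccdc121, Cngb3, Lamp5 and Cyp26a1.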

Other observations

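The tests of liver and globin transcripts and of the proximal tubule genes were chosen only after their results were seen; the other tests in this part were set out before the value they measure was looked at.

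A list of genes of principal cells, a cell type of the collecting duct, was written after the first results were seen but holds members not looked at before. It had a median log2 difference of 0.30 over 10 genes (95% bootstrap interval 0.062 to 0.78), with 6 of 10 higher in both knockout arrays and 0 lower. Fxyd4, a regulator of the sodium pump, was higher by 1.02 ± 0.11 (SE), Tmem45b by 0.89 ± 0.14 and the water channel Aqp3 by 0.78 ± 0.16, whereas Aqp2 differed by 0.24 ± 0.18 and Aqp4 by -0.092 ± 0.13. Camera in limma gave an adjusted p of 0.000183 over the 3 lists of this kind, and an adjusted p = 0.158 with an estimated correlation, while fry gave 0.00641. All 3 lists were chosen after results of these same arrays were seen. Their p-values are therefore not independent evidence, and adjusting over 3 lists does not cover that choice. The bootstrap intervals give the spread between genes, not between samples. In the same arrays liver and gut genes were higher by a median of 1.57 and skeletal muscle genes by 1.25, and no explanation for the principal cell genes was tested. Intercalated cell genes had a median of 0.51 over 4 genes (0.011 to 1.03), with a camera adjusted p of 0.0149 in limma, an adjusted p = 0.180 with an estimated correlation and 0.00315 with fry. The interval lies above 0, but 4 genes are too few to decide, and 2 of them were higher in both knockout arrays.

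Cyp26a1 and Aldh1a1, which act on opposite sides of retinoic acid metabolism, were both among the 12 lower genes named for the smallest unadjusted p, so a list of other retinoid pathway genes was tested. Its median log2 difference was -0.10 over 11 genes (95% bootstrap interval -0.28 to 0.050), with 5 lower and 3 higher in both knockout arrays. Camera gave an adjusted p of 0.0768, and an adjusted p = 0.323 with an estimated correlation, whereas fry in limma gave an adjusted p of 0.0430 for a shift to lower values, so whether the pathway moved as a whole stays open. Rdh10, which makes retinaldehyde, differed by -0.50 ± 0.063 (SE), Stra6, a retinol transporter, by -0.29 ± 0.057 and Dhrs3 by -0.23 ± 0.059, while Rara differed by 0.19 ± 0.070.

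Sequences that the array names only by a genomic interval were tested too. Among 3287 such sequences 167 were higher and 175 lower at an unadjusted p under 0.05, and none passed over all genes tested in limma with the default prior. The smallest p belonged to the interval from 8606683 to 8665783 on chromosome 10 of mm9, where the probes of both strands were higher in the knockout kidneys, by 0.89 ± 0.060 (SE) and 0.85 ± 0.073. An interval from 85609155 to 85615170 on chromosome 8 was higher by 0.90 ± 0.062. With the trended robust prior these probes passed (adjusted p of 0.00247 and 0.0325 on chromosome 10 and 0.00444 on chromosome 8). What these intervals transcribe was not analysed here.

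The genotype split gave 887 genes at least 1.5-fold apart without overlap and the highest of the other splits 443; it was the largest in 1 of the 3 splits, and 3 splits are too few for a share under 0.05. Sex of the embryos is argued against, since Xist differed by -0.027 and 0 of 5 Y-linked probes were well above background on any array. Of 611 such named genes other than Sall1, 0.982% (exact 95% interval 0.361% to 2.13%) lay among the 100 reference genes on each side of Sall1. Of the genes tested, 0.464% lay there (Fisher's exact test, two-sided p = 0.0638). Most of the 611 genes thus lay outside this window. The window held only 70 tested genes, so the share had to be small whatever the cause. It cannot decide on DNA of a parental strain around Sall1. The 6 neighbours among the 611 genes, chosen after their values were seen, were Adcy7, Irx6, Mt1, Mt2, Mylk3 and Pllp. Loss of Sall1, the presence of CreER, DNA of a parental strain around Sall1 and litter stay open. So do carried-over liver tissue and older embryos, which were examined below only on gene lists. DNA of a parental strain outside the window was not tested.

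Liver transcripts were higher in the knockout arrays, but they also differed between the control arrays, by a median of 0.79 over 14 genes (95% bootstrap interval 0.56 to 1.54; -0.13 between the knockout arrays), which carried-over liver tissue could give; the proximal tubule genes, by 0.020 between the same arrays, did not move along, though a pair of arrays cannot exclude expression by the tubule itself. For the proximal tubule list the difference between controls was 0.0896 of what the liver list would predict. The upper limit of 0.18 exceeds the limit of 0.11 set for excluding carry-over. This test cannot decide, because it takes the median of 13 genes. Only Hnf4a, Pdzk1 and Spp2 among them are named here as also made by liver, so carried-over liver need not move that median. Between the control arrays Hnf4a differed by 0.61, Pdzk1 by 0.020 and Spp2 by -0.999, which gives no common direction. The interval is drawn over genes, not over samples. Carry-over of liver therefore stays open for the proximal tubule genes. Older embryos in the knockout group stay open: the log2 ratio of adult over embryonic globins was 0.56 and 1.22 in control and 1.70 and 0.96 in knockout arrays, a difference of 0.44 (-0.56 to 1.43, 2 SE). Loss of Sall1 itself was not tested apart from these and stays open.

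Esr1 was at least 2.83-fold higher by 1 of its 3 probes in the knockout arrays, while the other probes differed by at most 0.22. This is consistent with that probe detecting the oestrogen receptor part of the CreER transcript, which the sample titles name only for the knockout group. The other probes were not well above background on any array, and the probe positions were not analysed here, so a change of the mouse gene itself is not excluded.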
